A study of Mus musculus with 27 samples.

How the data were processed

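Messenger RNA was sequenced in 27 mouse libraries, which fall into 3 tables of 9 libraries with 3 groups of 3 libraries each. The first table holds liver of healthy mice, liver of mice made fibrotic with carbon tetrachloride (CCl4, a solvent that injures hepatocytes), and liver of CCl4 mice that also received an extract of Sargassum japonica, a brown seaweed. The second holds organoids grown from the liver of mice given mineral oil, the vehicle of CCl4, organoids grown from CCl4 mice, and organoids of CCl4 mice treated with the extract for 24 h. The third holds untreated organoids grown from healthy mice, organoids given transforming growth factor beta 1 (TGF-β1, a cytokine that drives fibrosis) for 24 h, and organoids given TGF-β1 for 24 h and then the extract for a further 24 h. Per the labels' protocols, the organoids grew in domes of Matrigel and were then kept in a differentiation medium for 4 to 5 days before treatment. The labels do not say whether organoids given TGF-β1 alone were harvested at the end of the TGF-β1 step or together with those given the extract, and they give no dose of the extract, TGF-β1 or CCl4.

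Per the labels' protocols, RNA was extracted with TRIzol and 1.2 µg of it went into each library, made with a stranded TruSeq kit for mRNA. The genome build was mm10, per the submitters' processing notes. The aligner, the read counter and the gene annotation are not given in the sources used here. The values the authors deposited are log2 values per gene and library, not counts. From the values themselves, they are log2 per-million read counts (CPM) of an effective library size, with a prior count of 2 that was scaled to the library size. The effective library size was the read total multiplied by a scaling factor of the authors, which lay between 0.854 and 1.217 and whose method is not given in the sources used here. Taking off the prior count left whole multiples of 1 read: in every library 100% of the genes came within 0.05 of a whole number, and log2 values rebuilt from these reads differed from the deposited ones by at most 1.2e-07. The tables were normalized separately, so tests were run within a table, and levels set side by side across tables carry that limit. The organoid tables list 27178 genes each by Entrez identifier, of which 1319 had no symbol, and the tissue table lists 25859.

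The libraries held 44.5 to 64.8 M (mega) reads, so that 1 read was worth about the same small fraction of a CPM in each. All CPM values printed are reads per M of the authors' effective library size, without a prior count. Genes entered the tests when at least 3 libraries held the CPM that 10 reads give in a library of median size and the table held at least 15 reads of the gene. That left 15037 genes in the tissue table, 14836 in the table of organoids from mineral oil and CCl4 mice, and 14125 in the TGF-β1 table.

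The plan fixed before the data were examined was a count model, but the deposited values are log2 values and a test on that scale was chosen instead. Each table was therefore fitted with limma 3.58.1 in R 4.3.3 (lmFit on the log2 CPM of all 9 libraries with a mean for each of the 3 groups, and eBayes with a trend). Tests were two-sided, and a gene counted as changed at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are given with their standard errors on the scale of log2 CPM with the prior count, which understates the change of genes with few reads. A fold change against a group with no read in any library is given as a lower bound, from 3 reads per library. Differences between 2 effects were tested in one limma fit over both tables as the difference of the 2 contrasts, which removes a constant offset between tables. The labels do not say whether the numbered libraries of a group are separate animals or separate cultures.

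Before the data were examined, 34 gene lists were fixed, with 612 genes in all, covering matrix and fibrosis genes, signalling targets, liver metabolism, stress responses, the cell cycle and markers of cell types that liver or cultures could hold. Those with at least 3 tested members were tested with camera (limma), which asks whether the members of a list move apart from the other genes, with a preset correlation between genes of 0.01 and adjustment over the lists of a comparison. Each call was also computed with a correlation estimated from the libraries. Members that rose or fell are counted at an adjusted p over all genes tested and, in addition, with p-values adjusted over the list alone. The genes named were set by a rule fixed at the same time: 5 anchors of fibrosis (Acta2, Col1a1, Col3a1, Timp1 and Tgfb1), the 5 largest rises and the 5 largest falls among changed genes with a mean of at least 2 CPM and no overlap between the groups, and the 3 members with the smallest p of at most 6 called lists. For the tests of differences between effects, the 3 largest each way were named. Gene positions are those of the RefSeq annotation of GRCm38, which is build mm10.

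The limma steps were tested on simulated data made from the libraries' own means and sizes, with 200 changed genes per comparison. These were drawn from genes with a mean of at least 1 CPM, so the shares do not hold for genes with fewer reads. Of genes made to differ by a log2 of 1, 91% were recovered for CCl4 against healthy liver, 85% for the extract in liver, 69% for organoids of CCl4 against mineral oil mice, 63% for the extract in organoids of CCl4 mice, 76% for TGF-β1 and 66% for the extract after TGF-β1. At a log2 of 2 these shares were 99%, 100%, 85%, 88%, 92% and 92%. The tests of differences between effects recovered 49% to 52% at a log2 of 1 and 82% to 86% at a log2 of 2, and 13 to 15 of their 145 to 151 calls were false, which is more than the 5% the threshold aims at.

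Alternatives fixed in advance were other scalings (RLE size factors, library size only), other low-count filters, a fit of only the 6 libraries compared, a minimum log2 fold change of 1, the replicate number as a block, camera with an estimated correlation, the directional fry test, and leaving out each library in turn. Chosen after seeing the data were limma-voom on the recovered reads, a prior count of 0.5, and fits without 2 libraries of the TGF-β1 table that stood apart from the others of their groups. The numbers of libraries were not used to pair samples. Mitochondrially encoded genes could not be described, since none of the 13 members of that list has a row in the tables used here. Genes of families with near-identical copies, such as Mup, Cyp2c, Slc22a26 and Slc22a27, and Eif1ad genes, can share reads, and their values are uncertain.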

Results

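Transcripts were compared in liver and in liver organoids of mice, to see which fibrosis-related genes differ in each setting and whether a Sargassum japonica extract moves them. Values are mean CPM ± SD over the 3 libraries of a group (n = 3), log2 fold changes carry their SE, and adjusted p-values come from limma. The libraries held 45.1 to 64.8 M (mega) reads in liver, 45.9 to 54.8 M in organoids of mineral oil and CCl4 mice, and 44.5 to 60.6 M in the TGF-β1 experiment. Libraries of one group differed by more than read sampling, with a variance 3.4 to 81.9 times that of counting alone. Since the labels do not say that the libraries are separate animals or cultures, the p-values measure the spread between these libraries, which may be technical.

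The first principal component held 71.5% of the variance in liver, where it ran from the healthy to the CCl4 libraries with the extract-treated ones between. It held 67.3% in organoids of mineral oil and CCl4 mice and parted these groups, but mineral oil replicate 1 lay at -38.6 and replicates 2 and 3 at -120 and -131.7. In the TGF-β1 experiment the first component, with 62.1%, did not follow the treatment: untreated replicate 3 lay at 79.6 and TGF-β1 plus extract replicate 3 at 95.3, whereas the other 7 libraries lay between -27.2 and -23.2.

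**Figure D1:**
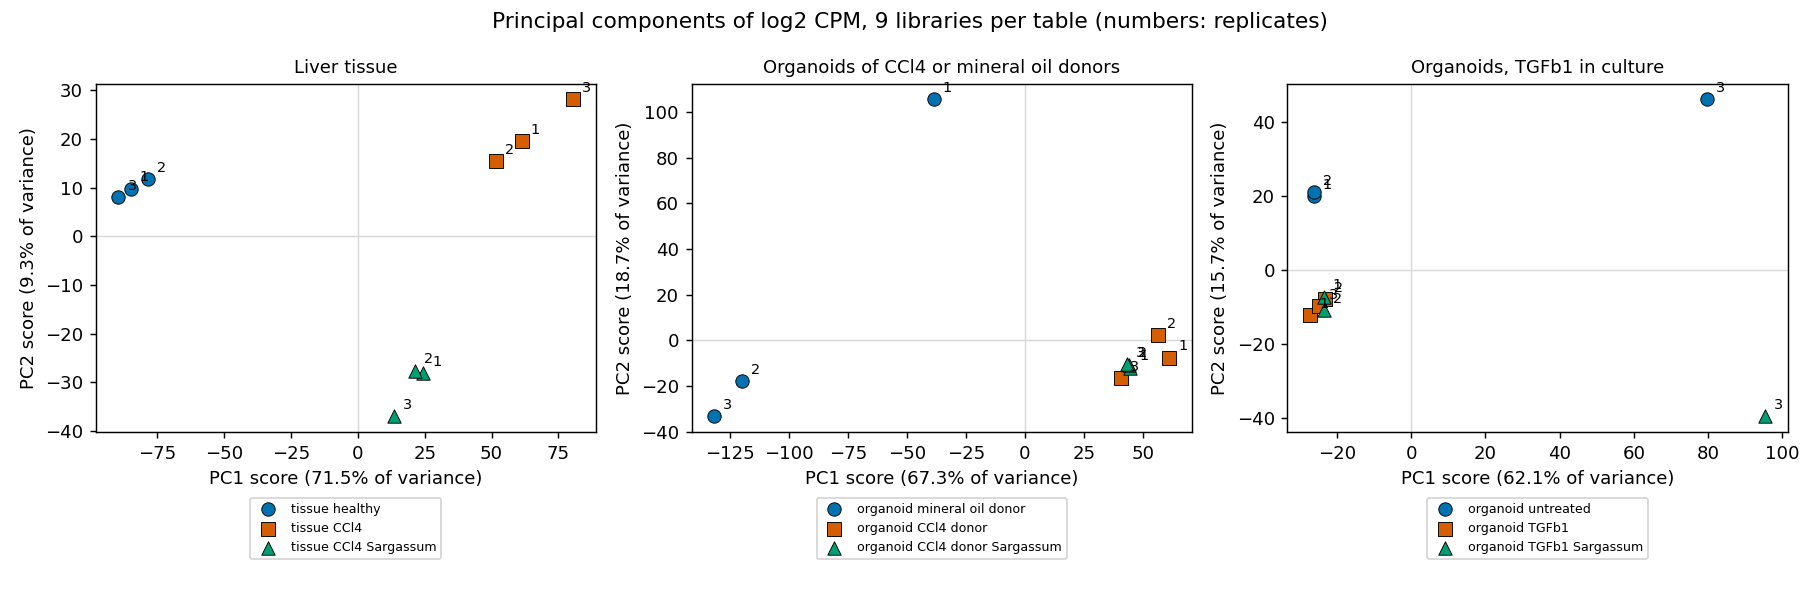
Principal components of the 9 libraries of each table, computed on log2 CPM of the tested genes, with component 1 on the x axis, component 2 on the y axis and one point per library coloured by group. Healthy liver lies at -89.5 to -78.4 and CCl4 liver at 51.7 to 80.5 on component 1, mineral oil replicate 1 lies apart at -38.6, and 2 libraries of the TGF-β1 experiment lie apart at 79.6 and 95.3.

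CCl4 liver was compared with healthy liver to see what the solvent changed in the tissue. Of 30 collagen and matrix genes 28 rose, of 19 matrix proteases and inhibitors 17, of 23 macrophage markers 20, and all tested G2/M and S phase genes. Of 21 bile acid genes 16 fell, of 21 cytochrome P450 genes 17 and of 25 hepatocyte markers 16, whereas the lists of cholesterol biosynthesis and fatty acid synthesis were not called (adjusted p = 0.31 and 0.374). The camera calls did not pass with an estimated correlation. Col1a1, a chain of type I collagen, rose from 3.96 ± 1.44 to 278 ± 91.5 CPM, a log2 fold change of 6.12 ± 0.27 (adjusted p = 1.5e-08). Acta2, the smooth muscle actin that marks activated stellate cells, rose from 1.8 ± 0.26 to 59.9 ± 48.6 CPM (4.75 ± 0.45, adjusted p = 5e-06). Timp1, an inhibitor of matrix proteases, rose from 0.14 ± 0.0886 to 6.68 ± 4.94 CPM, and Tgfb1 rose by 1.41 ± 0.16 on the log2 scale, from 7.29 ± 0.602 to 19.8 ± 4.83 CPM.

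For gene lists, brackets hold the same counts with p-values adjusted over the list alone ("list alone"), then the adjusted p of camera with its preset correlation and with an estimated one. Of the 30 genes of the collagen and matrix list, 28 rose and none fell (28 list alone; adjusted p = 1.98e-15 in camera, 0.286 estimated). Col3a1 rose by 4.71 ± 0.18, Col1a2 by 4.40 ± 0.19 and Col6a3 by 3.90 ± 0.16 on the log2 scale. All 22 genes of the G2/M list rose, with a median of 6.30 (22 list alone; adjusted p = 7.39e-18, 0.303 estimated). Ccnb1, the mitotic cyclin B1, went from 0.362 ± 0.373 to 71.6 ± 7.21 CPM. Cdc20, an activator of the anaphase-promoting complex, went from 0.463 ± 0.187 to 94.2 ± 15.6 CPM, and the mitotic kinase gene Cdk1 rose by 6.03 ± 0.22. The 19 S phase genes all rose too, with a median of 2.47 (19 list alone; adjusted p = 7.95e-13, 0.286 estimated). Among them were the replicative helicase genes Mcm5 (4.14 ± 0.14) and Mcm6 (3.97 ± 0.12). Beyond the lists, the largest rises included Depdc1a and Bub1, both of mitosis, and Cfap44, which had no read in healthy liver and was at least 130-fold higher in CCl4 liver.

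Of 23 macrophage and Kupffer cell markers, 20 rose and 1 fell (20 and 1 list alone; adjusted p = 4.54e-09, 0.303 estimated). Trem2, a receptor of lipid-associated macrophages, rose from 0.702 ± 0.143 to 23.1 ± 3.23 CPM, Itgax by 3.35 ± 0.15 and Ms4a7 by 4.35 ± 0.24. Of 19 matrix proteases and inhibitors, 17 rose (17 list alone; adjusted p = 3.83e-08, 0.286 estimated). The largest rise was that of the macrophage elastase gene Mmp12 at 6.15 ± 0.24, with Adam8 at 5.25 ± 0.25 and the plasminogen activator gene Plat at 4.81 ± 0.26. Stellate cell and myofibroblast markers rose in 15 of 19 cases and fell in 1 (16 and 1 list alone; adjusted p = 8.92e-05, 0.286 estimated). Of the 27 targets of TGF-β signalling, 20 rose and 2 fell (21 and 2 list alone; adjusted p = 4.05e-05, 0.308 estimated). Cholangiocyte and progenitor markers rose in 15 of 19 cases and fell in 1 (16 and 1 list alone; adjusted p = 0.000276, 0.308 estimated). Neutrophil markers rose in 9 of 10 cases (9 list alone; adjusted p = 0.000514, 0.303 estimated).

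Of 21 cytochrome P450 genes of drug metabolism, 17 fell and 2 rose, with a median of -1.11 (17 and 2 list alone; adjusted p = 2.42e-06, 0.308 estimated). Of 21 genes of bile acid synthesis and transport, 16 fell and 1 rose (16 and 1 list alone; adjusted p = 8.43e-07, 0.308 estimated). Slco1a1, a sinusoidal organic anion transporter gene, fell from 459 ± 74.5 to 13.3 ± 8.23 CPM, Cyp7b1 fell by 3.72 ± 0.17 and Cyp8b1, the sterol 12-alpha-hydroxylase gene, fell by 3.04 ± 0.28 on the log2 scale. In the list of PPARα targets and fatty acid oxidation, 19 of 22 genes fell and 1 rose (20 and 1 list alone; adjusted p = 3.63e-06, 0.308 estimated). Among 25 hepatocyte markers 16 fell and 1 rose (16 and 1 list alone; adjusted p = 8.44e-05, 0.308 estimated). The largest falls were those of Hsd3b5, a male-biased steroid reductase gene (211 ± 16.9 to 0.86 ± 0.642 CPM), the glutamate transporter gene Slc1a2 (193 ± 17.5 to 0.817 ± 0.567 CPM), and the major urinary protein genes Mup7, Mup17 and Mup1, whose reads can be shared among close copies.

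In all, 8143 of 15037 genes (54.2%) differed, 4314 higher and 3829 lower, and 3486 of them by a log2 of at least 1. Scaling by library size alone moved the median gene by 0.378 on the log2 scale and the split to 7261 higher and 1384 lower. The 17 list calls, 13 up and 4 down, rest on the preset correlation, since 0 of them passed with an estimated one. On build mm10, Col1a1 (Entrez gene 12842) lies on chromosome 11 from 94936224 to 94953042, Acta2 (11475) on chromosome 19 from 34240336 to 34255585, Col3a1 (12825) on chromosome 1 from 45311538 to 45349706, Timp1 (21857) on chromosome X from 20870166 to 20874737 and Tgfb1 (21803) on chromosome 7 from 25687002 to 25705077.

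The extract was tested in liver by comparing CCl4 mice that received it with CCl4 mice that did not. All tested genes of the G2/M and S phase lists fell, and so did 14 of 30 collagen and matrix genes. Of 21 cytochrome P450 genes 17 rose, of 21 bile acid genes 12 and of 22 genes of PPARα and fatty acid oxidation 10. The camera calls of these lists did not pass with an estimated correlation. Col1a1 fell from 278 ± 91.5 to 80.8 ± 16.1 CPM, a log2 fold change of -1.75 ± 0.27 (adjusted p = 0.001). Acta2 fell from 59.9 ± 48.6 to 8.38 ± 3.49 CPM (-2.65 ± 0.45, adjusted p = 0.0021). Col3a1 fell from 448 ± 121 to 189 ± 20.7 CPM (-1.21 ± 0.18, adjusted p = 0.00079). Timp1 fell from 6.68 ± 4.94 to 1.64 ± 0.481 CPM (-1.80 ± 0.47, adjusted p = 0.021). That call ended without CCl4 replicate 3 (-1.24, adjusted p = 0.069), without extract replicate 2 (-1.71, adjusted p = 0.07) or without extract replicate 3 (-1.67, adjusted p = 0.081). Tgfb1 was 19.8 ± 4.83 CPM without and 14.8 ± 1.11 CPM with the extract (-0.39 ± 0.16, adjusted p = 0.1). That difference passed with scaling by library size alone (-0.63, adjusted p = 0.023) and without CCl4 replicate 2 (-0.52, adjusted p = 0.047).

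All 22 G2/M genes fell, with a median of -2.58 (22 list alone; adjusted p = 1.12e-22, 0.415 estimated). The 19 S phase genes all fell, with a median of -1.78 (19 list alone; adjusted p = 6.7e-24, 0.229 estimated). Bub1b, a spindle checkpoint gene, fell by 2.37 ± 0.18, Aurka by 2.35 ± 0.19, and the mitotic motor gene Kif11 by 2.47 ± 0.21 on the log2 scale, and the helicase genes Mcm6 and Mcm5 had log2 fold changes of -2.15 ± 0.12 and -2.43 ± 0.14. Of the 30 collagen and matrix genes, 14 fell and none rose (20 and 1 list alone; adjusted p = 3.62e-06, 0.415 estimated). Col1a2 was at -1.46 ± 0.19 and Col6a3 at -1.14 ± 0.16. The list of stellate cell and myofibroblast markers was not called, with 4 of 19 lower and 1 higher past the test (adjusted p = 0.0871), and with 10 lower and 1 higher with library size only (adjusted p = 0.335). Of 19 matrix proteases and inhibitors, 8 fell and 1 rose (9 and 1 list alone; adjusted p = 0.00326, 0.415 estimated). Of 27 TGF-β targets, 3 fell and 1 rose (3 and 1 list alone; adjusted p = 0.00597, 0.518 estimated), and with library size only 12 fell and 0 rose. Of 23 macrophage and Kupffer cell markers, 4 fell and 1 rose (4 and 1 list alone; adjusted p = 0.0278, 0.686 estimated). This call was lost when only library size was scaled (adjusted p = 0.0721). Apart from the lists, the largest falls were those of Cdh17, a cadherin of liver and intestine (6.27 ± 1.28 to 0.638 ± 0.254 CPM), the mitotic genes Oip5 and Ska1, Trdc, the constant segment of the T cell receptor delta chain, and Inava.

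Of 21 cytochrome P450 genes, 17 rose and none fell, with a median of 0.888 (20 and 0 list alone; adjusted p = 2.67e-12, 0.415 estimated). Cyp2c29 rose from 630 ± 487 to 3940 ± 115 CPM (2.91 ± 0.37), Cyp2c37 by 2.67 ± 0.31 and Cyp3a25 by 1.75 ± 0.26. Of 21 bile acid genes, 12 rose and none fell (15 and 0 list alone; adjusted p = 3.42e-07, 0.415 estimated). Among them were Slc27a5, the bile acyl-CoA synthetase gene (377 ± 107 to 946 ± 87.9 CPM), the sterol 27-hydroxylase gene Cyp27a1 (1.36 ± 0.20) and Fgfr4, a receptor for intestinal FGF signals (0.75 ± 0.09). Of 22 PPARα and fatty acid oxidation genes, 10 rose (11 list alone; adjusted p = 1.14e-05, 0.415 estimated). Acaa1b rose by 1.76 ± 0.24, Cyp4a10 by 1.76 ± 0.30 and Angptl4 by 1.23 ± 0.17. Of 25 hepatocyte markers,, 9 rose (11 list alone; adjusted p = 0.000138, 0.415 estimated). The largest rises were those of Slc22a27 and Slc22a26, close copies of organic anion transporter genes, the thyroxine-binding globulin gene Serpina7 (36.9 ± 29.5 to 277 ± 73.8 CPM), Csad, an enzyme gene of taurine synthesis (29.5 ± 12.4 to 244 ± 129 CPM), and Cyp2c29. Blood haemoglobin genes moved in the same libraries: 2 of 5 rose (4 adjusted over the list alone), with a median of 1.21 (adjusted p = 0.00885, adjusted p = 0.415 with an estimated correlation).

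With the extract 2871 of 15037 genes differed, 1403 higher and 1468 lower, and 777 of them by a log2 of at least 1. Leaving out a library lowered this to 1863 without CCl4 replicate 1, 1802 without CCl4 replicate 3, 1801 without extract replicate 1, 1685 without extract replicate 2 and 1452 without extract replicate 3. With library size alone the median gene moved by -0.23 on the log2 scale and the split was 640 higher and 3600 lower. Of the 15 list calls 6 were up and 9 down, and 0 passed with an estimated correlation.

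Most genes that differed with the extract had moved the other way with CCl4. Of the 8143 genes changed by CCl4, 2440 (30%) changed back, 1230 that had risen and 1210 that had fallen, and they made up 85% of the genes changed by the extract. A further 46 genes moved on in the same direction. Independent lists would share 421 and 357 genes. In simulations without any effect at most 1 gene moved back. These held no CCl4 effect either, so hardly any gene could be called in both comparisons. That number therefore does not give how many genes the shared libraries move back where CCl4 has an effect. Over the genes called for CCl4, a median of 38% of the CCl4 change was reversed in the extract-treated libraries. The same value was 10.9% in organoids of CCl4 mice, where no gene passed for the extract, so not all of the 38% need be its effect. In liver, 1022 of the 2440 genes still differed from healthy liver. Because both comparisons use the CCl4 libraries, a negative correlation arises without any effect. Pearson's r across genes was -0.709 and lay between -0.516 and -0.468 in simulations with no effect. The simulated r comes from noise alone, so it does not give the share of the observed r that the shared libraries cause. The covariance was -0.471 against a simulated -0.029. With 3 CCl4 libraries these could not be split, so part of the excess may come from the shared libraries. The count fell to 1543 without CCl4 replicate 3, 1489 without extract replicate 2 and 1331 without extract replicate 3. Scaled by library size alone, 3140 genes went up and then down and 493 down and then up.

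**Figure D2:**
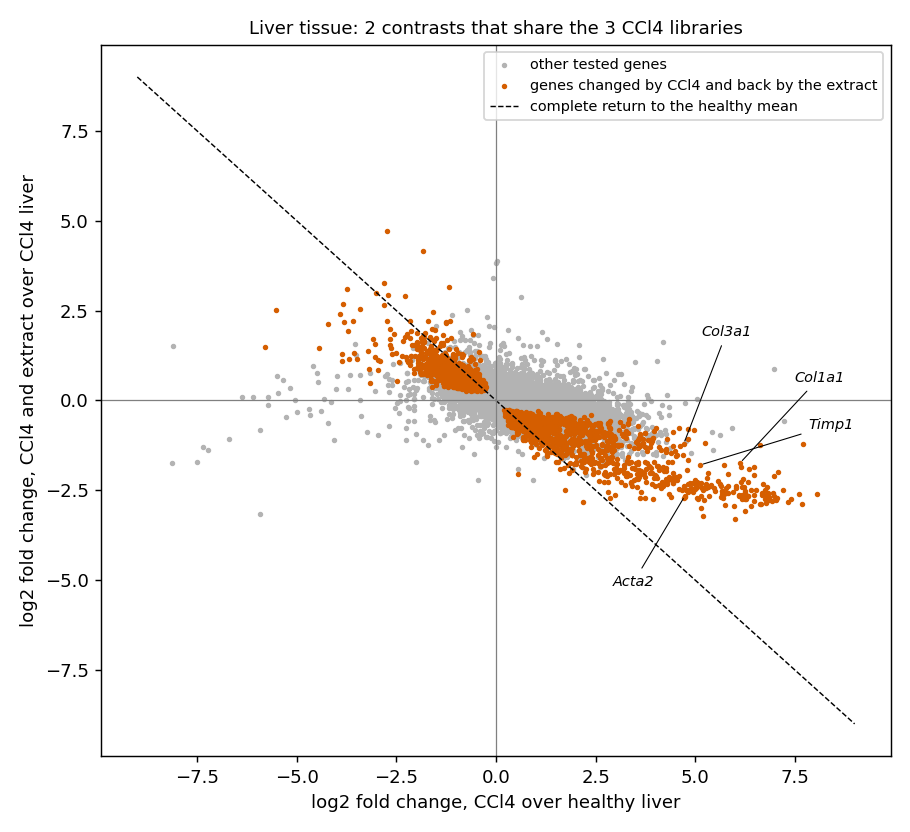
Log2 fold change of CCl4 against healthy liver (x axis) and of extract-treated against untreated CCl4 liver (y axis), with one point per tested gene and orange points for the 2440 genes that changed with CCl4 and changed back with the extract. The cloud runs from upper left to lower right, with r = -0.709 and a covariance of -0.471. In simulations without any effect the shared CCl4 libraries gave r of -0.516 to -0.468 from noise alone, and a covariance of -0.029.

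Organoids grown from CCl4 mice were compared with organoids from mineral oil mice to see what a culture keeps of the fibrotic donor. The labels name no animals or culture lines, so a difference between lines cannot be told apart from an effect of the donor's treatment. Of 23 tested interferon response genes 17 fell in organoids of CCl4 mice, of 15 YAP targets 9, of 26 TGF-β targets 9 and of 14 collagen and matrix genes 7. Of 16 hepatocyte markers 8 rose, and of 13 bile acid genes 9. The camera calls of these lists did not pass with an estimated correlation. Ifit1, an interferon-induced antiviral gene, fell from 45.5 ± 13.4 to 0.848 ± 0.285 CPM (-5.68 ± 0.29, adjusted p = 1.7e-05). Alb, the albumin gene, rose from 0.955 ± 0.793 to 95.3 ± 52.1 CPM (7.30 ± 1.06, adjusted p = 0.0013). Col1a1 was low in both groups and fell from 1.79 ± 0.573 to 0.116 ± 0.134 CPM (-3.84 ± 0.60, adjusted p = 0.0019), the reverse of its rise in CCl4 liver. Acta2, at 0.0541 ± 0.0606 and 0.0702 ± 0.0332 CPM, and Col3a1, at 0.00664 ± 0.0115 and 0 CPM, had too few reads for a test. Tgfb1 was 11 ± 1.84 and 8.28 ± 4.1 CPM (-0.55 ± 0.40, adjusted p = 0.3).

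Of 23 interferon response genes, 17 fell and none rose, with a median of -1.67 (18 and 0 list alone; adjusted p = 1.56e-08, 0.388 estimated). They include Oasl2 at -5.71 ± 0.42 and Ifit3 at -4.08 ± 0.23. Most macrophage and Kupffer cell markers were hardly read in these cultures. Their median was 0 CPM in both groups, with 3 of 23 members above a mean of 1 CPM, so the next counts do not show a difference in macrophages. Of 6 tested macrophage and Kupffer cell markers, 5 fell (5 list alone; adjusted p = 0.0146, 0.388 estimated), with a median of -1.56. Of 15 YAP targets, 9 fell (10 list alone; adjusted p = 0.00069, 0.388 estimated). The matricellular gene Ccn1 went from 112 ± 12 to 30.8 ± 10.8 CPM, with Amotl2 at -1.93 ± 0.27 and the receptor kinase gene Axl at -4.63 ± 0.62. Of 26 TGF-β targets, 9 fell and 2 rose (9 and 2 list alone; adjusted p = 0.00838, 0.388 estimated). Ski and Smad6, both feedback inhibitors of the pathway, fell by 0.87 ± 0.07 and 0.85 ± 0.08, and the transglutaminase gene Tgm2 fell by 1.13 ± 0.11 on the log2 scale. Of 13 matrix proteases and inhibitors, 8 fell (8 list alone; adjusted p = 0.00838, 0.427 estimated). These include the protease inhibitor genes Timp3 (2400 ± 1820 to 58.2 ± 25 CPM) and Timp2 (-1.69 ± 0.30) and the membrane protease gene Mmp14 (-0.92 ± 0.11). Timp1 was 1.32 ± 0.555 and 0.531 ± 0.246 CPM. Its fall (-1.27 ± 0.43, adjusted p = 0.047) was lost with library size only (-1.24, adjusted p = 0.061) and with only the 6 libraries fitted (-1.27, adjusted p = 0.1). It was also lost without mineral oil replicate 2 (-1.30, adjusted p = 0.1), mineral oil replicate 3 (-0.96, adjusted p = 0.15), CCl4 replicate 1 (-0.92, adjusted p = 0.14) or CCl4 replicate 2 (-1.30, adjusted p = 0.095). Of the 14 collagen and matrix genes that could be tested, 7 fell (8 and 1 rise list alone; adjusted p = 0.0317, 0.451 estimated). In the list of the unfolded protein and integrated stress response, 10 of 19 fell and 2 rose (11 and 3 list alone; adjusted p = 0.00838, 0.388 estimated). The chaperone gene Hspa5 fell from 1190 ± 88 to 577 ± 64.5 CPM, Creld2 by 1.39 ± 0.12 and Sdf2l1 by 0.84 ± 0.06 on the log2 scale.

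Of 16 hepatocyte markers, 8 rose and 2 fell (10 and 2 list alone; adjusted p = 0.0317, 0.388 estimated). Of 13 bile acid genes, 9 rose and 1 fell (9 and 1 list alone; adjusted p = 0.0125, 0.388 estimated). Slc51a, a basolateral bile acid transporter gene, was among them (6.99 ± 11.8 to 197 ± 31.9 CPM). Its log2 fold change varied between 6.08 and 10.06 over the alternatives. Both lists were low in culture. Over all its members, the hepatocyte list had a median of 3060 CPM in healthy liver. In organoids of mineral oil and CCl4 mice its median was 0.373 and 1.49 CPM, and that of the bile acid list was 0.452 and 1.92 CPM. In the same comparison genes of intestinal absorptive cells, a set chosen after the results were seen, rose in 8 of 30 cases and fell in 0, and without mineral oil replicate 1 they rose in 26. Of 22 PPARα and fatty acid oxidation genes, 13 rose and 2 fell (13 and 2 list alone; adjusted p = 0.009, 0.388 estimated). Cyp4a10 rose by 4.24 ± 0.46 and Acaa2 by 0.94 ± 0.11. Pdk4, an inhibitor of pyruvate oxidation, fell from 3.01 ± 0.407 to 0.0515 ± 0.045 CPM. Fatty acid synthesis genes fell in 10 of 17 cases and rose in 2 (11 and 2 list alone; adjusted p = 0.0102, 0.388 estimated). The largest rises also included the urea cycle gene Otc (0.0399 ± 0.069 to 12.5 ± 5 CPM), Mgat4c, and the stem cell receptor gene Lgr5, which had no read in organoids of mineral oil mice and was at least 130-fold higher in those of CCl4 mice. The largest falls were those of the adenylate kinase gene Ak4 (50.5 ± 7.7 to 0.0434 ± 0.0445 CPM), Rasgrf1 (75 ± 6.69 to 0.107 ± 0.099 CPM), the sodium-calcium exchanger gene Slc8a1 and Tnk1, and Pdpn, the podoplanin gene, which was at least 400-fold lower.

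In these organoids 5963 of 14836 genes (40.2%) differed, 3032 higher and 2931 lower, and 2634 of them by a log2 of at least 1. Without mineral oil replicate 1, which stood apart, 9004 genes differed, 4702 higher and 4302 lower, and a fit of only the 6 libraries compared gave 3803. Of the 14 list calls 3 were up and 11 down, and 0 passed with an estimated correlation.

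**Figure D3:**
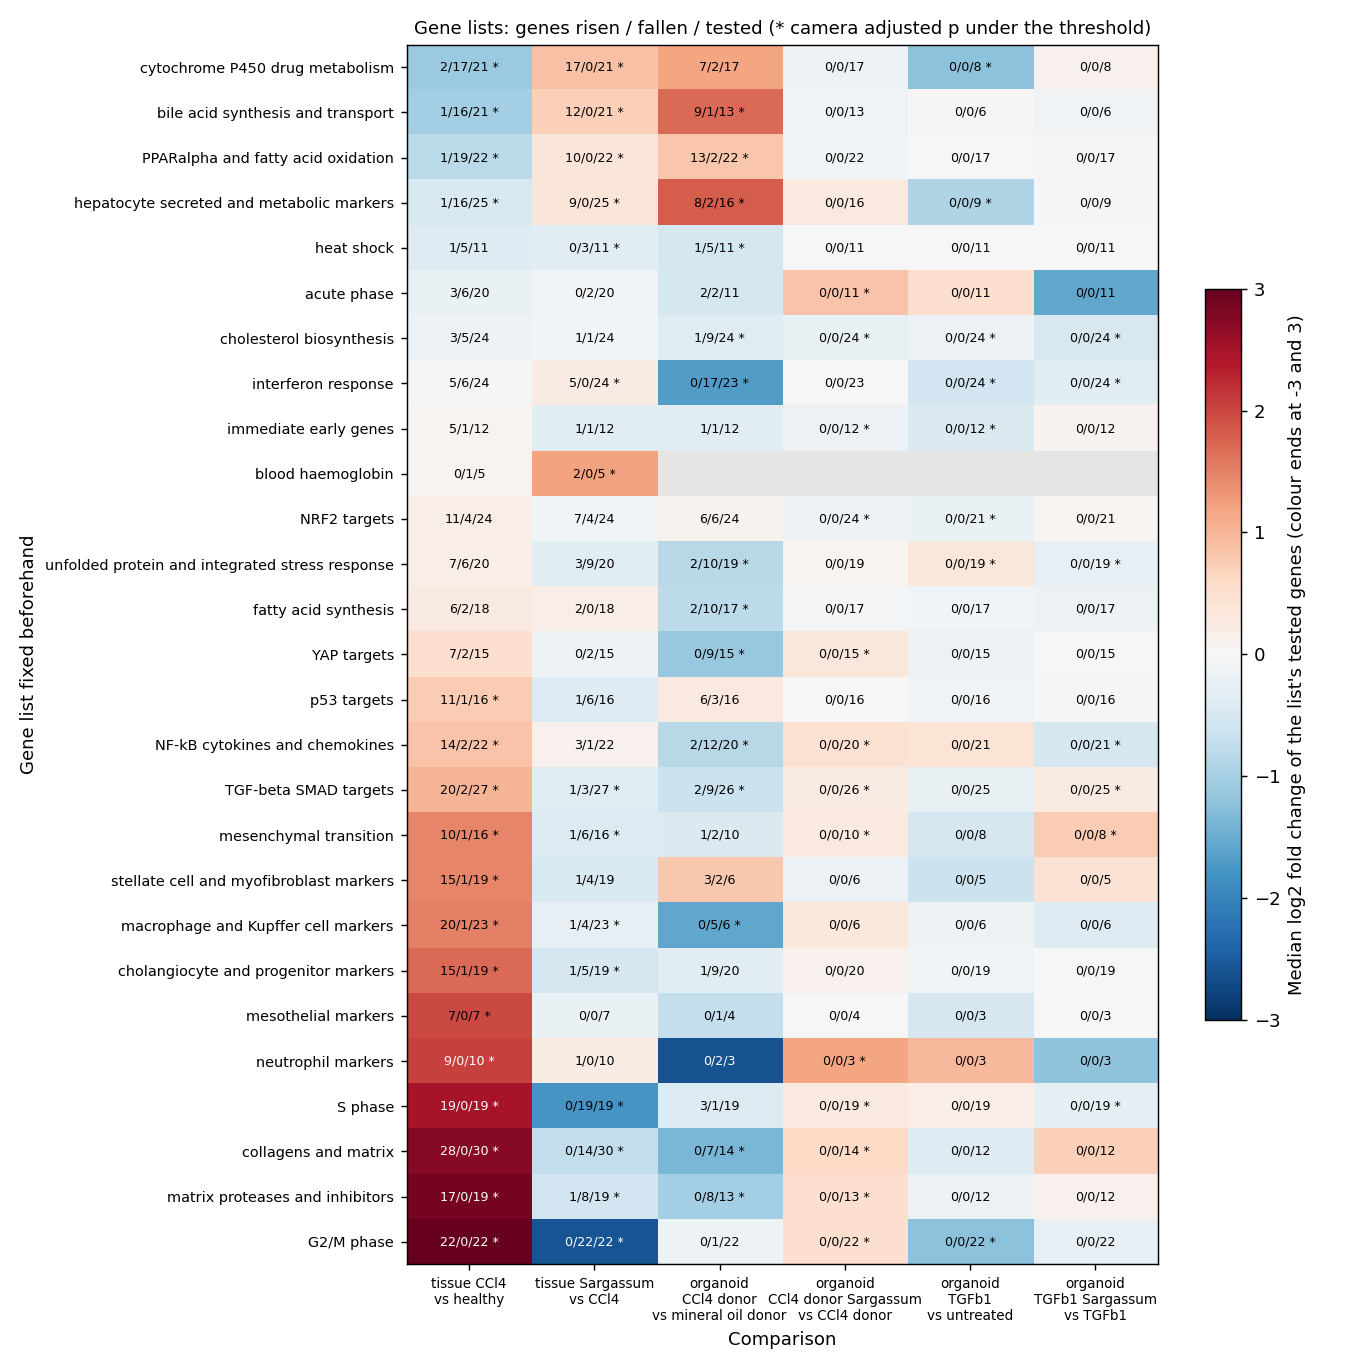
Heat map of the gene lists called in at least one of the 6 comparisons, with the comparisons as columns, colour for the median log2 fold change of a list's tested members, an asterisk for a camera call and, in each cell, how many members rose and fell and how many were tested. The G2/M list had a median of 6.30 in CCl4 against healthy liver and -2.58 with the extract in liver, and the columns of the extract in organoids hold no gene that rose or fell.

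The extract was also applied to organoids of CCl4 mice for 24 h. No gene passed the test: limma gave 0 of 14836 genes, limma-voom on the recovered reads gave 0, and 271 genes had an unadjusted p under 0.05 where 742 arise by chance. A number under that of chance is no evidence against an effect. The fit took its spread from all 9 libraries, among them mineral oil replicate 1, which stood apart. Without that library 0 genes passed too. Tgfb1 was 8.28 ± 4.1 CPM without and 12 ± 1.5 CPM with the extract (0.68 ± 0.40, adjusted p = 1). Col1a1 was 0.116 ± 0.134 and 0.185 ± 0.0912 CPM (0.79 ± 0.60, adjusted p = 1) and Timp1 was 0.531 ± 0.246 and 0.853 ± 0.244 CPM (0.70 ± 0.43, adjusted p = 1). Acta2 (0.0702 ± 0.0332 and 0.0753 ± 0.0378 CPM) and Col3a1 (0 CPM in both) were too low for a test.

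Camera called lists with the preset correlation, but no member passed on its own, and neither an estimated correlation nor fry kept a call. All 24 genes of cholesterol biosynthesis were lower with the extract, with a median of -0.225 and none past the test (0 list alone; adjusted p = 9.29e-14 in camera, 0.365 estimated). The lanosterol demethylase gene Cyp51 was 521 ± 66.5 and 429 ± 20.9 CPM (-0.27 ± 0.10), and Msmo1 and Pmvk of the same pathway differed by -0.23 ± 0.09 and -0.25 ± 0.10. All 13 matrix proteases and inhibitors were higher, with a median of 0.498 (0 list alone; adjusted p = 4.57e-05, 0.442 estimated). Timp3 was at 58.2 ± 25 and 148 ± 21.6 CPM. Cytokine and chemokine genes of NF-κB were higher in 15 of 20 cases, with a median of 0.466 (0 list alone; adjusted p = 0.000522, 0.365 estimated). The neutrophil chemokine gene Cxcl5 was at 68.1 ± 22.2 and 145 ± 9.35 CPM and Cxcl1 at 8.78 ± 2.47 and 13 ± 0.98 CPM. G2/M genes were higher in 21 of 22 cases (median 0.5; 0 list alone; adjusted p = 0.000811, 0.643 estimated). Collagen and matrix genes were higher in 13 of 14 cases (median 0.594; 0 list alone; adjusted p = 0.00109, 0.442 estimated). TGF-β targets were higher in 19 of 26 cases (median 0.253; 0 list alone; adjusted p = 0.00101, 0.442 estimated). Tgfb3 was at 0.5 ± 0.2 and 2 ± 0.265 CPM. Camera called 13 lists, 10 up and 3 down, 6 without CCl4 replicate 1, 0 with an estimated correlation and 0 by fry.

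In untreated organoids of healthy mice, TGF-β1 was given to mimic a fibrotic signal in culture. With all libraries, 3 genes passed, all lower with TGF-β1, and each of these calls was lost when the replicate number was a block (adjusted p = 0.064 for each, with log2 fold changes of -4.29 for Cyp4a12a, -2.32 for Aoc1 and -0.53 for Pdk2 as without it). Cyp4a12a, a fatty acid omega-hydroxylase gene, fell from 21.1 ± 7.47 to 1.06 ± 0.487 CPM (-4.29 ± 0.40, adjusted p = 0.031). The diamine oxidase gene Aoc1 fell from 3.82 ± 0.298 to 0.736 ± 0.093 CPM (-2.32 ± 0.20, adjusted p = 0.031), and Pdk2, a pyruvate dehydrogenase kinase gene, from 47.3 ± 0.955 to 32.7 ± 0.871 CPM (-0.53 ± 0.05, adjusted p = 0.038). Fibrosis anchors did not pass: Tgfb1 was 34.7 ± 11.9 and 42.9 ± 1.72 CPM (0.37 ± 0.24, adjusted p = 0.58), and without both libraries that stood apart Tgfb1 was 41.5 ± 1.8 and 42.9 ± 1.72 CPM (0.05 ± 0.06). Timp1 was 1.77 ± 0.437 and 2.45 ± 0.254 CPM (0.48 ± 0.33, adjusted p = 0.6) and Col1a1 0.86 ± 0.0706 and 0.625 ± 0.244 CPM (-0.50 ± 0.57, adjusted p = 0.76). Acta2 (0.121 ± 0.0144 and 0.0184 ± 0.0193 CPM) and Col3a1 (0.0765 ± 0.133 and 0 CPM) were too low for a test. On build mm10, Cyp4a12a (Entrez gene 277753) lies on chromosome 4 from 115299046 to 115332815, Aoc1 (76507) on chromosome 6 from 48895255 to 48909188 and Pdk2 (18604) on chromosome 11 from 95026258 to 95041371.

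All 22 G2/M genes were lower with TGF-β1, with a median of -1.22 and none past the test over all genes (15 list alone; adjusted p = 3.75e-16, 0.591 estimated). The cyclin gene Ccnb2 was 18.6 ± 6.97 and 4.06 ± 0.574 CPM (-2.14 ± 0.32, adjusted p = 0.095), Cdc20 16.7 ± 6.27 and 4.75 ± 0.866 CPM, and Cenpf 39.9 ± 15.3 and 9.9 ± 2.67 CPM. The 8 cytochrome P450 genes tested were lower, with a median of -1.22 (5 list alone; adjusted p = 2.4e-05, 0.519 estimated). Cyp2d10 was at 38.4 ± 17.3 and 6.15 ± 1.12 CPM (-2.56 ± 0.30, adjusted p = 0.061). In the list of the unfolded protein and integrated stress response 17 of 19 genes were higher, with a median of 0.349 (6 higher and 1 lower list alone; adjusted p = 0.000407, 0.591 estimated). The pseudokinase gene Trib3 was 17.8 ± 1.45 and 62.1 ± 2.15 CPM (1.81 ± 0.23, adjusted p = 0.061) and Ddit3, the CHOP gene, 13.3 ± 1.58 and 23.1 ± 0.795 CPM (0.80 ± 0.13, adjusted p = 0.11). Atf3 was 11.6 ± 1.45 and 7.61 ± 0.789 CPM (-0.61 ± 0.14, adjusted p = 0.19). Immediate early genes were lower in 9 of 12 cases (4 list alone; adjusted p = 0.00619, 0.591 estimated). Egr1 was at 53.4 ± 5.47 and 21.6 ± 1.23 CPM and the phosphatase gene Dusp1 was at 20.1 ± 1.27 and 8.16 ± 1.65 CPM. Interferon response genes were lower in 19 of 24 cases, with a median of -0.574 (0 list alone; adjusted p = 0.000384, 0.707 estimated). In a fit of only the 6 libraries compared, Ccnb2 (adjusted p = 0.046), Cyp2d10 (0.044), Trib3 (0.0018), Egr1 (0.016) and Dusp1 (0.042) passed.

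The number of calls varied between fits: limma-voom gave 1, a fit of only the 6 libraries gave 55. In addition, 1747 genes had an unadjusted p under 0.05 where 706 arise by chance. Without untreated replicate 3, Aoc1 and Pdk2 no longer passed (adjusted p = 0.053 for each). With any one of the other 5 libraries of the comparison left out, none of the 3 genes passed, at an adjusted p of 0.083 to 0.28 for Cyp4a12a, 0.15 to 0.25 for Aoc1 and 0.15 to 0.38 for Pdk2. Their log2 fold changes stayed at -4.63 to -4.04, -2.41 to -2.23 and -0.55 to -0.51 over all alternatives. The count was 0 without untreated replicate 1, untreated replicate 2 or any one of the 3 TGF-β1 libraries. Untreated replicate 3 and TGF-β1 plus extract replicate 3 stood apart from their groups. Without both, in a fit chosen after seeing the data that left 3 libraries against 2, 3310 genes differed, 1631 higher and 1679 lower (3114 by limma-voom). Cyp4a12a (-4.57 ± 0.28, adjusted p = 4.5e-07), Aoc1 (-2.29 ± 0.24, adjusted p = 3.1e-05) and Pdk2 (-0.55 ± 0.05, adjusted p = 2.2e-05) were among them. These changes were small, with a median absolute log2 of 0.29 and 333 of at least 1. All 22 G2/M genes fell there, with a median of -1.03 (Ccnb2 -1.85 ± 0.21, adjusted p = 7.4e-05). In the stress response list 9 genes rose and 3 fell, with Trib3 at 1.84 (adjusted p = 2.3e-07), Chac1, a glutathione-degrading enzyme gene, at 1.56 ± 0.14 and the asparagine synthetase gene Asns at 0.96 ± 0.08. Col1a1 remained without a call at -0.53 ± 0.34 (adjusted p = 0.29). Other genes of the matrix and of TGF-β signalling, named after their values were seen, passed. Pmepa1, a feedback inhibitor of the pathway, rose by 0.94 ± 0.05 (adjusted p = 2.3e-07), Col4a1 by 0.37 ± 0.08, Col4a2 by 0.24 ± 0.07 and Loxl1, a collagen cross-linking enzyme gene, by 2.07 ± 0.63. The proteoglycan gene Bgn had a log2 fold change of -0.88 ± 0.10. Of 12 collagen and matrix genes 4 rose and 1 fell, and the list was not called (adjusted p = 0.46). Nor was that of TGF-β targets, with 5 up and 6 down of 25 (adjusted p = 0.674).

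**Figure D4:**
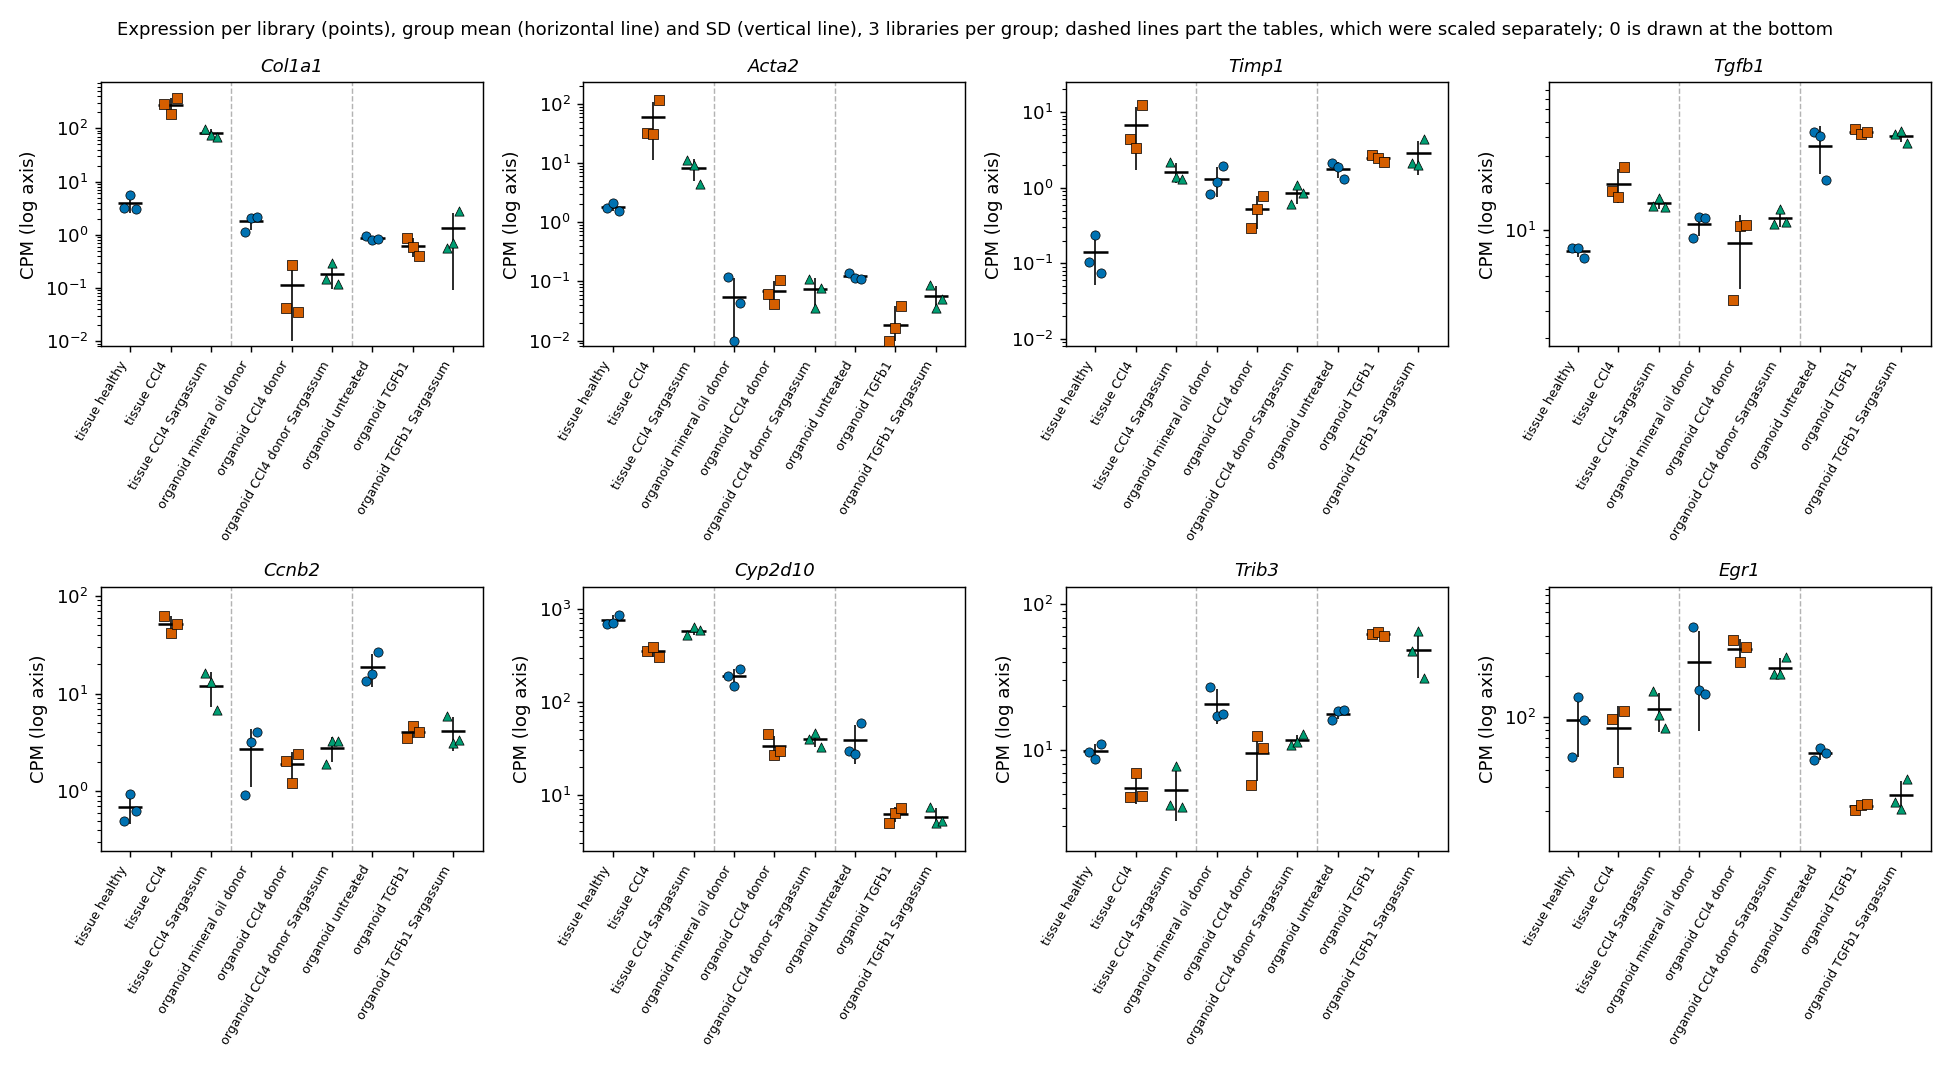
CPM of Col1a1, Acta2, Timp1, Tgfb1, Ccnb2, Cyp2d10, Trib3 and Egr1 on log axes, with one point per library and a bar at the mean of each of the 9 groups. Col1a1 averages 278 CPM in CCl4 liver and under 2 CPM in every organoid group, and Trib3 averages 17.8 CPM in untreated and 62.1 CPM in TGF-β1 organoids.

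The extract after TGF-β1 was compared with TGF-β1 alone. No gene passed the test: limma gave 0 of 14125 genes, limma-voom gave 0, and 272 genes had an unadjusted p under 0.05 where 706 arise by chance. That deficit is no evidence against an effect, and without both libraries that stood apart 918 genes had such a p. In simulated data 66% of genes made to differ by a log2 of 1 were recovered here, so differences of that size can be missed. The simulated genes had a mean of at least 1 CPM, and the share does not hold for lower genes. Tgfb1 was 42.9 ± 1.72 CPM with TGF-β1 and 40.4 ± 3.65 CPM with the extract added (-0.09 ± 0.24, adjusted p = 0.89). Timp1 was 2.45 ± 0.254 and 2.84 ± 1.35 CPM (0.12 ± 0.33, adjusted p = 0.89), and Col1a1 0.625 ± 0.244 and 1.35 ± 1.26 CPM (0.76 ± 0.57, adjusted p = 0.77). Without both libraries that stood apart Col1a1 was 0.625 CPM in both groups (0.06 ± 0.34) and Timp1 2.45 ± 0.254 and 2.07 ± 0.11 CPM (-0.24 ± 0.18). Acta2 (0.0184 ± 0.0193 and 0.0576 ± 0.026 CPM) and Col3a1 (0 CPM in both) were too low for a test.

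Genes of cholesterol biosynthesis were lower in 23 of 24 cases, with a median of -0.478 (0 list alone; adjusted p = 1.79e-06, 0.8 estimated). Ebp was at 169 ± 3.3 and 134 ± 38.5 CPM and Mvk, the mevalonate kinase gene, at 33.5 ± 1.79 and 24.5 ± 10.3 CPM. Their median without the 2 libraries that stood apart was -0.079 (adjusted p = 1.25e-05). S phase genes were lower in 18 of 19 cases, with a median of -0.272 (0 list alone; adjusted p = 0.000976, 0.8 estimated). Without those libraries the median was -0.017 (adjusted p = 0.99). Genes of mesenchymal transition were higher in 7 of 8 cases (0 list alone; adjusted p = 0.00906, 0.8 estimated). The integrin gene Itga5 was 0.563 ± 0.16 and 33.2 ± 56.1 CPM, and without those libraries it was 0.563 ± 0.16 and 0.798 ± 0.31 CPM (0.46 ± 0.37). This call too was lost without those libraries (adjusted p = 0.27) and with library size only (adjusted p = 0.0547). Camera called 7 lists, 2 up and 5 down, 2 without replicate 3 of TGF-β1 plus extract, 3 without both libraries that stood apart, 0 with an estimated correlation and 0 by fry. Without both libraries no gene passed in limma or limma-voom (0 in each), with 918 at an unadjusted p under 0.05 and a smallest adjusted p of 0.076.

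The effects were then compared between settings. The controls were healthy mice for liver and mice given mineral oil for organoids, which also grew in culture after the donor's treatment. Vehicle, culture and cell type are therefore part of the difference between these contrasts, and a difference between culture lines may be. The effect of CCl4 on liver and that of a CCl4 donor on organoids differed in 6042 of 13116 genes tested in both (5839 by limma-voom). Of these 2940 were more positive and 3102 more negative in organoids. With library size alone that split was 1525 and 4152. In all 2088 genes were called in both with opposite signs. Genes called in the same direction numbered 1044, of which 511 rose and 533 fell. Independent lists of these sizes would share 716 and 704 (odds ratios of 0.586 and 0.641). The count of same-direction genes was 1582 without mineral oil replicate 1 and, with library size alone, 1171 up and 160 down. Slc1a2 and Cyp2c38 fell in liver and rose in organoids, with differences of 10.38 ± 0.86 and 9.68 ± 0.78 on the log2 scale. Ly6d, a surface antigen gene, rose by 6.48 ± 0.25 in liver and had a log2 fold change of -7 ± 0.75 in organoids, a difference of -13.48 ± 0.98 (adjusted p = 5.4e-06). The lactoferrin gene Ltf and Pdpn also rose in liver and fell in organoids.

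Liver in mice and organoids in culture differ in tissue and in how the extract was given. These cannot be told apart from a different action of the extract. The log2 fold change with the extract differed between liver and organoids of CCl4 mice in 2137 of 13116 genes (2065 by limma-voom). In organoids it was more positive for 1147 of these and more negative for 990. With library size alone 3569 genes differed (3263 and 306). The count was 1403, 1409 and 1314 without replicate 1, 2 or 3 of the extract-treated organoids and 1355 without extract replicate 3 of liver. The mitotic genes Depdc1a and Espl1 and the DNA glycosylase gene Neil3 fell in liver by 2.87 ± 0.43, 2.63 ± 0.37 and 2.93 ± 0.72, and in organoids their values were 1.18 ± 0.89, 1.06 ± 0.83 and 1.35 ± 0.78, none of which passed. Serpina7, Csad and Cyp2c37 rose in liver by 3.15 ± 0.39, 2.98 ± 0.38 and 2.67 ± 0.31 and were -0.06 ± 0.47, -0.11 ± 0.14 and -0.15 ± 0.54 in organoids. Between the 2 organoid models the extract's effect differed in 0 of 13538 genes by limma and 0 by limma-voom, with 422 at an unadjusted p under 0.05.

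The effect of a CCl4 donor and that of TGF-β1 differed in 2937 of 13538 genes (2821 by limma-voom), 1313 more positive and 1624 more negative in organoids of CCl4 mice. Alb, Itih2 and the carboxylesterase gene Ces2a were more positive there, by 8.95 ± 1.37, 8.59 ± 1.53 and 10.86 ± 2.98, and Ltf, Rasgrf1 and Tnk1 more negative, by -9.15 ± 1.61, -8.32 ± 0.78 and -8.31 ± 0.64. The call of Ces2a (adjusted p = 0.028) was lost in 7 of the fits that left out 1 library, at an adjusted p of 0.05 to 0.067. The count was 5784 without mineral oil replicate 1, 1918 without mineral oil replicate 2, and 1868, 1857 and 1827 without TGF-β1 replicate 1, 2 or 3. TGF-β1 shared 2 called genes of the same direction with CCl4 liver and 0 with organoids of CCl4 mice. Without both libraries that stood apart these numbers were 859 (421 up and 438 down, with 403 and 401 for independent lists) and 776 (289 up and 487 down, with 320 and 327). In the same fits 891 genes were called with opposite signs in CCl4 liver and TGF-β1 organoids (804 for independent lists), with a Spearman correlation across genes of 0.00214. For organoids of CCl4 mice and TGF-β1 organoids 601 were (647 for independent lists), with a correlation of 0.0276. In the organoids no gene that CCl4 or TGF-β1 had changed moved back with the extract (0 in both by limma, where the extract had 271 and 272 genes at an unadjusted p under 0.05 and 0 by limma-voom).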

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

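The tests of the libraries that stood apart, of the matrix genes and of the intestinal genes were chosen after the results were seen. The tests of differences between effects and the regroupings of libraries were planned before. No rule for outliers was applied, since groups of 3 libraries are too small for one.

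Mineral oil replicate 1 stood apart from replicates 2 and 3. An ordinary CCl4 library under a wrong label would correlate with the CCl4 organoids as they do with each other. The mean r of replicate 1 with them was 0.924 against a lowest of 0.979 among them, so that account was excluded. An atypical CCl4 library was not excluded, since the mean r of replicate 1 with its own group was 0.917. Were replicate 1 a mixture of RNA of both groups, no gene should fall far under all other libraries. But 17 genes were at least 10 times under the lowest of the other 8 libraries, against at most 3 in any other library, so a mixture was excluded. Among the 17 was the Y-linked gene Eif2s3y, with 0 CPM against 79.6 CPM or more in each of the other 8 libraries. Whether this reflects the sex of the donor or a change in the culture was not tested, and either would be part of the comparison of the donor groups. No biological explanation was tested, and a separate animal or culture line remains open.

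Untreated replicate 3 and TGF-β1 plus extract replicate 3 stood apart on the same side of principal component 1. On component 2 they lay apart from each other, at 46.2 and -39.6. Their deviations from their groups correlated at 0.72, as they would if both came from 1 other preparation or culture line. An exchange of labels with other libraries of these groups as the cause was excluded, since the mean r of untreated replicate 3 with TGF-β1 plus extract replicates 1 and 2 was 0.944 against a lowest of 0.985 among the other 7 libraries, and low depth was excluded as well, with 53 M reads against a lowest of 44.5 M. An exchange of these 2 labels with each other stays open: of 333 genes called for TGF-β1 without both libraries at a log2 of at least 1, 74.5% went from untreated replicate 3 to TGF-β1 plus extract replicate 3 in the direction of TGF-β1, which argues against an exchange but lies under the 75% set before this test was run. A culture line that differs by donor animal stays open too, because the labels do not name the animals.

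Of 14 tested collagen and matrix genes 7 fell in organoids of CCl4 mice (adjusted p = 0.0317 for the list, 0.451 with an estimated correlation), and 28 of 30 rose in CCl4 liver. Stromal cells carried into the mineral oil cultures would bring other stromal genes with Col1a1, but the highest ratio of such a gene to Col1a1 was 0.0037, against a lowest of 0.24 in CCl4 liver, so carry-over was excluded. Mineral oil replicate 1 alone was excluded too, since 8 genes of the list fell without it (adjusted p = 0.0124). No biological explanation was tested.

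The contrast of CCl4 with its control differed between organoids and liver in 6042 genes. That difference includes those of vehicle, culture and cell type, and may include one between culture lines. The largest differences were those of Slc1a2 (10.38), Cyp2c38 (9.68), Cyp2c29 (8.96 ± 2.1), Ly6d (-13.48), Ltf (-11.56) and Pdpn (-10.96) on the log2 scale. That of Cyp2c29 varied between 7.09 and 11.11 over the alternatives. Pdpn had no read in organoids of CCl4 mice, so the size of its difference rests on the prior count. The extract's effect differed between organoids of CCl4 mice and liver in 2137 genes, most for Neil3 (4.28), Depdc1a (4.05), Espl1 (3.69), Serpina7 (-3.21), Csad (-3.08) and Cyp2c37 (-2.82). The effect of a CCl4 donor differed from that of TGF-β1 in 2937 genes, most for Ces2a (10.86), Alb (8.95), Itih2 (8.59), Ltf (-9.15), Rasgrf1 (-8.32) and Tnk1 (-8.31).

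Every split of the 6 libraries of a comparison into 3 and 3 was tested, and 10 splits are too few for a share under 0.05. For genes, the real split or a split that called as many was found 1 time for CCl4 liver (8143 genes, highest other 0), 1 time for the extract in liver (2871, highest other 0), 1 time for organoids of CCl4 mice (5963, highest other 0) and 1 time for TGF-β1 (3, highest other 0). It was found 10 times for both tests of the extract in organoids (0, highest other 0). For lists, the numbers were 5 for CCl4 liver (17 lists, highest other 24), 4 for the extract in liver (15, highest other 20), 2 for organoids of CCl4 mice (14, highest other 18), 1 for the extract in these (13, highest other 9), 2 for TGF-β1 (8, highest other 9) and 10 for the extract after TGF-β1 (7, highest other 10).

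Of 100 regroupings over both effects, the real one included, 1 reached the 6042 genes of the CCl4 effect (highest other 3363), 1 the 2137 of the extract's effect in organoids against liver (highest other 1999), 2 the 2937 of a CCl4 donor against TGF-β1 (highest other 3278) and 100 the 0 of the extract in both organoid models. The 2440 genes that moved back in liver were reached by 3, the highest with 4510 genes exchanging the healthy and CCl4 labels whole, and the 0 genes of both organoid models by 100 each. The 1044 genes shared by CCl4 liver and organoids of CCl4 mice were reached by 2 (highest other 2088, as many as were called with opposite signs), and they are fewer than the 716 up and 704 down of independent lists. The 2 shared with TGF-β1 were reached by 1 (highest other 0) and the 0 shared by both organoid models by 100 (highest other 1).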

How the results depend on the processing

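The alternatives were compared by the number of genes or lists called, and no named gene was called in the opposite direction (0 of 177 results, with 1849 of 1911 values unchanged, 37 weaker and 25 stronger). DESeq2 and the other count models of the plan were not run, although whole reads could be recovered. Of the tests on recovered reads only limma-voom was run. RLE size factors changed no call of a named gene. Where a count moved, the cause was not tested unless a reason is given.

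Lists depended most on the correlation between genes: with an estimated one the calls went from 17, 15, 14, 13, 8 and 7 to 0 in each of the 6 comparisons. The directional fry test gave 24 lists for CCl4 liver, 13 for the extract in liver, 18 for organoids of CCl4 mice, 0 for the extract in organoids of CCl4 mice, 2 for TGF-β1 and 0 for the extract after TGF-β1. For the last, 3 lists were left without both libraries that stood apart.

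A minimum log2 change of 1 left 3486 genes for CCl4 liver, 777 for the extract in liver and 2634 for organoids of CCl4 mice. It left 3825, 706 and 1506 genes in the 3 tests of differences between effects that had calls, 252 genes shared by CCl4 liver and organoids of CCl4 mice, and 1 shared by CCl4 liver and TGF-β1. A fit of only the 6 libraries compared gave 3803 genes for organoids of CCl4 mice and 55 for TGF-β1. The number of genes called for TGF-β1 went from 3 to 0 without a low-count filter, to 1 with limma-voom and to 3310 without both libraries that stood apart, a fit chosen after seeing the data. The difference of the extract's effect between liver and organoids went from 2137 to 3569 with library size only. Genes shared by CCl4 liver and TGF-β1 went from 2 to 1 with library size only and to 859 without both libraries. Those shared by organoids of CCl4 mice and TGF-β1 went from 0 to 776.

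In the 6 comparisons the replicate number did not pair samples: the smallest correlation between libraries of one number was 0.03 to -0.15 over the comparisons, and at most 2 of 3 libraries fitted best with their own number. Untreated against TGF-β1 plus extract was not among them, and the 2 libraries of these groups that stood apart share replicate number 3 and library number 5. TGF-β1 replicate 2 has library number 5 too and did not stand apart, at -23.2 on component 1. As a block the replicate number gave 8241, 2893, 5734, 0, 1 and 0 genes in the 6 comparisons, and the library number as a block gave 0 for TGF-β1. The 1 gene called for TGF-β1 with the replicate block was none of Cyp4a12a, Aoc1 and Pdk2 (adjusted p = 0.064 for each). The block also gave 1304 genes for the extract's effect in organoids against liver and 0 shared by CCl4 liver and TGF-β1.

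Leaving out each library in turn gave 7112 to 7983 genes for CCl4 liver, 1452 to 2902 for the extract in liver, 4260 to 9004 for organoids of CCl4 mice, 0 to 3 for TGF-β1 and 0 for both tests of the extract in organoids. Lists went from 17 to 19, 12 to 16, 13 to 16, 6 to 14, 6 to 10 and 2 to 9. Differences between effects went from 5153 to 7380 for CCl4, 1314 to 2612 for the extract in organoids against liver and 1827 to 5784 for a CCl4 donor against TGF-β1. Genes that moved back in liver went from 1331 to 2862, genes shared by CCl4 liver and organoids of CCl4 mice from 753 to 1582, and genes shared by CCl4 liver and TGF-β1 from 0 to 2.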

Other observations

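Genes of intestinal absorptive cells were read in organoids of CCl4 mice. The brush border phosphatase gene Alpi was at 395, 834 and 526 CPM in organoids of CCl4 mice and at 1110, 3.91 and 1.09 CPM in mineral oil replicates 1, 2 and 3. The protease gene Mep1a was at 558, 604 and 371 CPM against 90.7, 1.04 and 0.342 CPM, and the intestinal transcription factor gene Cdx2 at 249, 163 and 160 CPM against 120, 16.8 and 11.7 CPM, with 0 CPM in liver. A set of 30 absorptive genes, chosen after the first of them were seen, was predicted to rise in more than 0.5 of its members, and 8 rose while 0 fell, so the prediction was not met. Camera placed the set up at p = 0.0025 with the preset and p = 0.51 with an estimated correlation. Without mineral oil replicate 1, 26 of 30 rose, and these camera p-values, computed over genes, were 5.9e-10 and 0.086. Whether the cultures hold cells with an intestinal program remains open.

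Muscle genes were found in untreated replicate 1, with Acta1 at 41.9, Tnnt3 at 18.6, Myh1 at 14.9 and Ckm at 12.6 CPM. The homeobox gene En1 was at 115, 106 and 103 CPM in the mineral oil organoids and between 3.11 and 3.66 CPM in those of CCl4 mice. In the libraries that stood apart the mucin gene Muc5b was at 0.589 CPM (untreated replicate 3, against 88.7 and 89.6) and 0.469 CPM (TGF-β1 plus extract replicate 3, against 34.2 and 31.7), and Tff2 at 78.2 CPM against 562 and 597 and at 9.12 CPM against 275 and 270. Fn1 was at 486 CPM in that last library against 4.09 and 3.92 CPM. The cholangiocyte keratin gene Krt19 averaged 0.756 ± 0.154 CPM in healthy and 4.19 ± 4.55 CPM in CCl4 liver, and 1960 CPM or more in every organoid group.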
